A study of Caenorhabditis elegans with 4 samples.

How the data were processed

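ChIP-seq was performed on whole L2 hermaphrodites of strain OP361. Per the labels' protocols, larvae were synchronized, grown at 20 °C on plates with *E. coli*, crosslinked in 2% formaldehyde and sonicated, 10% of the cleared lysate was kept as Input, and the rest was incubated with an affinity-purified goat antibody against GFP. The labels give 2 ChIP and 2 Input samples, grouped and numbered here by their titles. Peak lists were used for both ChIP samples and for a combined call of the series. The Input samples entered no comparison.

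Per the file headers, the intervals are on WormBase WS180, and the source column of each file names PeakSeq as the caller. The value deposited by the authors for each interval is a q value (an adjusted p-value), and it was equal to the q value attribute on every line of all 3 files. The aligner, the version and thresholds of the caller, the control used for each call and the way the replicates were combined are not given in the sources used here. PeakSeq is built to compare a ChIP library with a control, and its q values fall as the number of reads rises, so they rank peaks within a list and do not measure occupancy. The files give no read counts. Depth is therefore unknown, and intervals on shares cover counting error only.

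The replicate 2 list held 1320 lines but 760 distinct intervals: 560 were on 2 identical lines, and 200 were on 1 line. Of those 200, 196 overlapped exactly 1 other, with edges that differed by a median of 13.5 bp. Overlapping lines were therefore merged into 662 regions, each with the smallest q value of its lines. The other lists had no overlapping lines. Overlap meant at least 1 shared bp. A replicate 1 region was paired with the replicate 2 region of largest overlap. Overlap was tested against 9999 circular shifts per chromosome, correlations and differences of medians against 100000 permutations, chromosome shares by exact binomial tests and by 100000 multinomial draws with Benjamini-Hochberg adjustment, the central 50% of the chromosomes by an exact binomial test, and closeness of peaks by 9999 random placements. Because the binomial tests take peaks as independent, chromosome shares were also tested with each run of peaks at most 5 kb apart counted as 1. Because shares sum to 100%, they were also tested without II, and without I and II. Shares have 95% Wilson intervals. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

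The tests, some of the alternatives and the rule for named items were written before the data were examined. The closing section names the alternatives that were added later. The rule named the 15 strongest combined-list peaks found in both replicates and the strongest unshared peak of each replicate, by coordinates where no annotation fits the build. The recovery of combined-list peaks by chromosome, the test of neighbouring peaks, the circular-shift test of the central 50%, the loci missing from the combined list and the regions in neither replicate were chosen after seeing the data. The gene table at hand is on assembly WBcel235 and gives no WS180 positions, so planned tests of promoters, noncoding genes, gene and tissue-marker lists, sequence motifs and the nhr-21 and unc-119 loci were not run. Chromosome lengths were to come from a header or a WS180 reference; the largest peak end over the 3 lists was used, which leaves out sequence beyond the last peak.

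The overlap test was tested on simulated data. Of 100 pairs of unrelated lists with the real widths and chromosome counts, 1% had p at or below 0.05. These lists were placed at random without clustering and tested with fewer shifts than the real lists. The rate therefore does not cover clustered peaks. In a further pair, 200 shared peaks were planted with identical coordinates. All 200 were found, which was certain by construction and checks the counting only. Alternatives covered the overlap rule, stricter lists, other random placements, the unmerged replicate 2 intervals, chromosome II left out and each replicate's own list in place of the combined one.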

Results

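The series mapped where the *Caenorhabditis elegans* protein NHR-21 is bound on the genome in larvae of the L2 stage, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). NHR-21 belongs to the nuclear hormone receptors, a family of DNA-binding transcription factors that is greatly expanded in nematodes. The strain, OP361, carries an nhr-21 transgene fused to GFP and a 3xFLAG tag in an unc-119 mutant background, with unc-119 as the rescuing marker, so that bound DNA could be collected with an antibody against GFP. The labels describe 4 libraries, 2 ChIP and 2 Input, where Input is sonicated chromatin taken before the antibody step. The free-text descriptions of the samples are at odds with their titles: the libraries titled Input are described with the antibody, and those titled ChIP as input DNA. The titles and source names were followed here. Peak lists were analysed for ChIP replicate 1, for ChIP replicate 2 and for a combined call, 3 lists in all. The Input libraries were not analysed here, so no statement is made on the background at a peak. The lists hold intervals and q values without read counts, and the depth of each library is therefore unknown. All coordinates are WormBase WS180, the build named in the file headers, counted from 1. No annotation of that build was used here, so peaks are given by position and the genes beside them are not named.

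Binding was called at 1137 regions in the combined list, at 409 in replicate 1 and at 662 in replicate 2. The combined regions covered 1.26 Mb and the replicate regions 0.45 Mb and 0.719 Mb. Most regions were narrow, with a median width of 690 bp in the combined list (interquartile range 468 to 1253 bp), 734 bp in replicate 1 and 711.5 bp in replicate 2. Only 19 combined regions were wider than 5 kb. The q values, as assigned by the authors' peak caller PeakSeq, ran from 8.78e-253 to 8.73e-05 in the combined list, from 2.11e-102 to 4.59e-05 in replicate 1 and from 2.84e-219 to 6.33e-05 in replicate 2. A q value of at most 1e-10 was held by 446 combined regions, by 149 of replicate 1 and by 250 of replicate 2.

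The smallest q value of the combined list belonged to a region near the high-coordinate end of the X chromosome, at X 17419437 to 17422408 (q = 8.78e-253). Here and below, the strength of a region means the rank of its q value within its list and not the level of occupancy. This region also ranked first in replicate 1 (q = 2.11e-102) and was the third strongest of replicate 2 (q = 5.05e-161). It was followed by V 723660 to 728347, with q = 2.45e-215 in the combined list, 1.55e-91 in replicate 1 and 7.55e-126 in replicate 2. The next was II 8811125 to 8814695, with q = 7.07e-151, 5.52e-46 and 1.33e-77 in the same order. It lies beside the locus II 8816917 to 8821513, which was strong in both replicates but absent from the combined list. Whether extra transgene copies or high Input signal contribute at this region was not tested. The region V 8038843 to 8041664 had q = 3.61e-135, 3.78e-54 and 9.13e-88. A broader region, V 6220702 to 6230162, was 9461 bp wide and had q = 4.69e-126, 3.44e-48 and 5.1e-82. The 15 strongest combined regions were all called in both replicates, with combined q values down to 1.69e-97 and widths from 1134 to 9461 bp. The other 10 were V 6275170 to 6278830, II 11841454 to 11846770, X 8035842 to 8036975, X 14525311 to 14526572, IV 8527292 to 8531064, IV 16167145 to 16171690, IV 14032551 to 14034807, X 6736213 to 6738077, X 16929289 to 16931944 and III 3862862 to 3867786. Of the 15, 5 lay on X, 4 on V, 3 on IV, 2 on II, 1 on III and 0 on I. Among the 15, the rank differed most between the replicates at IV 8527292 to 8531064 (combined q = 1.22e-107), which was the 18th strongest signal of replicate 2 (q = 1.18e-60) and the 97th of replicate 1, where it was split into 3 regions, the best with q = 7.34e-15. Next came X 6736213 to 6738077 (combined q = 4.58e-98), the 10th of replicate 2 (q = 1.69e-77) and the 38th of replicate 1, where it was split into 2 regions, the best with q = 7.13e-29.

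**Figure D1:**
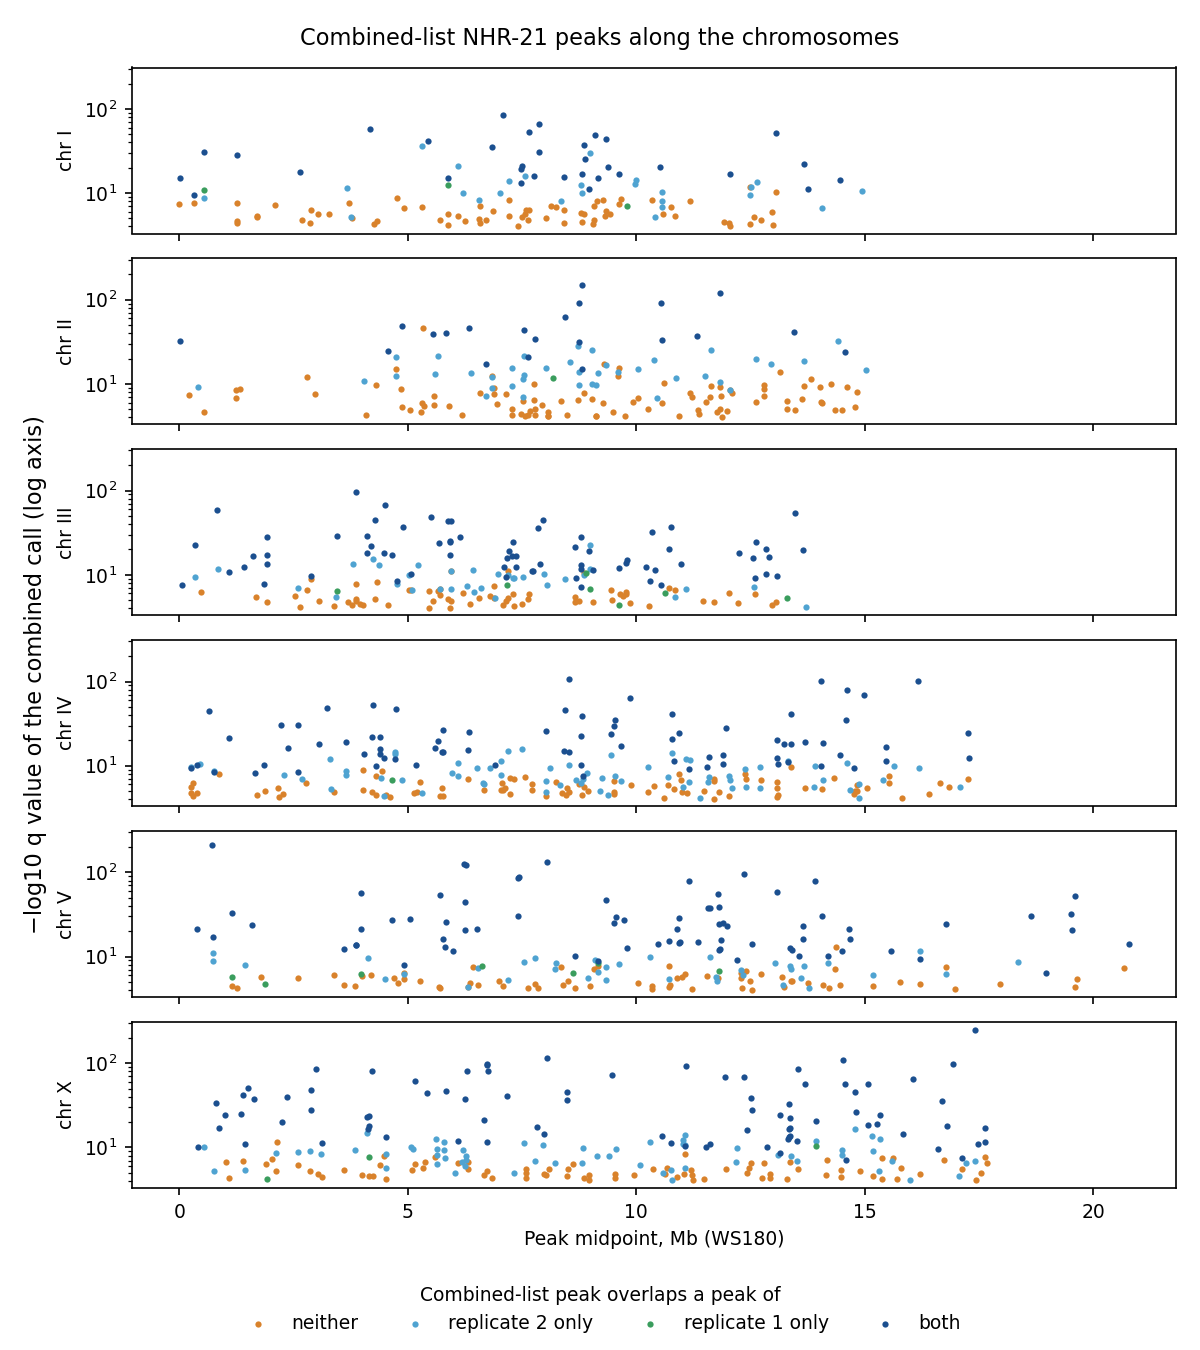
Each point is 1 of the 1137 combined-list peaks, placed by its midpoint in Mb (WS180) on the horizontal axis and by −log10 q value on a logarithmic vertical axis, with 1 panel per chromosome. Colours show whether the peak overlaps a peak of both replicates (365), of replicate 1 only (22), of replicate 2 only (271) or of neither (479), and the strongest peak is the point at the right end of X.

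The replicates were compared to ask how many binding sites were called in each library. Of the 409 replicate 1 regions, 386 overlapped a replicate 2 region, which is 94.4% (95% Wilson interval 91.7 to 96.2%). In the other direction 379 of 662 replicate 2 regions, or 57.3% (53.5 to 61.0%), overlapped a replicate 1 region. Random circular shifts of the peaks along each chromosome gave 6.03 ± 2.68 overlapping replicate 1 regions (mean and SD over the shifts) and at most 66 (one-sided permutation p = 0.0001, the smallest these shifts can give). The 100 strongest regions of each replicate were all found in the other. Among the weaker 50% of each list, 182 of 205 replicate 1 regions were shared against 90 of 331 replicate 2 regions. When replicate 2 was limited to its 409 strongest regions, 335 replicate 1 regions, or 81.9%, were shared. The strongest unshared region of replicate 2 was I 5310971 to 5313852 (q = 1.01e-16), and that of replicate 1 was V 3982176 to 3983025 (q = 1.5e-07). Both were in the combined list. Nothing in the labels says whether the replicates came from separate cultures.

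Replicate 2 regions that replicate 1 shared were stronger and wider than those found in replicate 2 alone. Their median −log10 q value was 12.2 (n = 379 regions) against 5.46 (n = 283 regions), a difference of 6.74, and their median width was 906 bp against 578 bp. Both differences exceeded every one of 100000 random reassignments (two-sided permutation p = 1e-05, the smallest they can give). Over the 386 overlapping pairs, the q values of the replicates were ranked alike, with Spearman's rho of 0.84 and Pearson's r of 0.84 on the −log10 scale (permutation p = 1e-05 for each). This correlation runs across peaks, which are not independent replicates. The −log10 q value was higher in replicate 2 in 343 of the 386 pairs, with a median ratio of 1.41. The −log10 q value also depends on sequencing depth, which is unknown here, so the ratio cannot be read as a difference in binding.

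**Figure D2:**
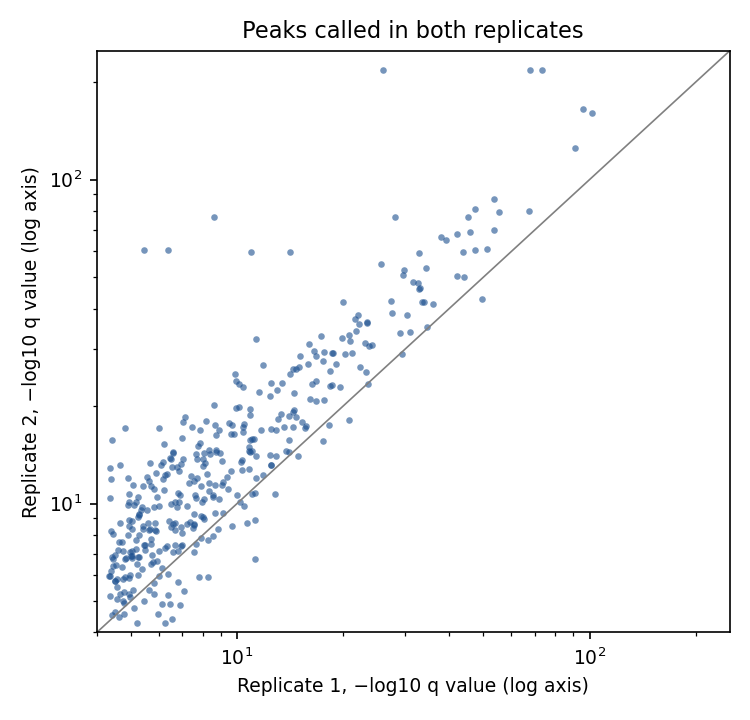
Each point is 1 of the 386 overlapping pairs of regions, with −log10 q value in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, both logarithmic, and the line marks equal values. Replicate 2 lies above the line in 343 pairs, and the points that share 1 height to the upper left are broad replicate 2 regions that matched several replicate 1 regions.

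The combined list was set against the replicate lists to ask how far it rests on regions called in each library alone. Of its 1137 regions, 365 or 32.1% (29.5 to 34.9%) overlapped a region of both replicates, 271 or 23.8% only of replicate 2, 22 or 1.93% only of replicate 1, and 479 or 42.1% (39.3 to 45.02%) of neither. The regions in both were the strong ones, with a median −log10 q value of 20.6 against 5.36 for those in neither. In 10 groups of about equal size by q value, the share called in at least 1 replicate fell from 99.1% in the strongest group to 7.89% and 10.6% in the last 2. How the replicates entered the combined call is not given in the sources used here, and a call made from the same libraries would not be independent evidence. In the other direction, 6 replicate 1 regions and 11 replicate 2 regions had no counterpart in the combined list. Of these, 1 region of replicate 1 (q = 4.4e-05) and 7 of replicate 2 (q of 6.45e-06 or larger) were weak, while 5 regions of replicate 1 and 4 of replicate 2 came from 2 loci with strong signal in both replicates. The locus II 8816917 to 8821513 held the 2nd strongest region of each replicate (q = 2.01e-96 and 1.66e-165). The locus V 12548609 to 12557738 held the strongest region of replicate 2 (q = 2.84e-219) and the 4th and 5th strongest of replicate 1 (q = 6.34e-74 and 1.1e-68). No combined-list interval fell in either locus.

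The share of combined-list regions found in a replicate differed between chromosomes. It was lowest on II, where 62 of 158 regions, or 39.2% (31.97 to 47.02%), were found in at least 1 replicate, and next lowest on I, with 61 of 132 or 46.2% (37.9 to 54.7%). It lay between 62.1% and 64.5% on III, IV, V and X. Against random chromosome labels within the 10 groups by q value, 95.2 ± 3.92 regions (mean and SD) were expected on II and 75.6 ± 3.69 on I. The deficits had two-sided permutation p, adjusted over 6 chromosomes by Benjamini-Hochberg, of 6e-05 on II and 0.00024 on I. This expectation pools all 6 chromosomes, and IV, V and X lay above it (permutation test, adjusted p = 0.0017, 0.00279 and 0.0101), while III did not depart from it past the threshold (0.189). On II replicate 1 found 22 regions against 56.4 expected and replicate 2 found 61 against 92.2. On I replicate 2 found 58 against 73.1 (permutation test, adjusted p = 0.00016), but the deficit in replicate 1, 36 against 43.3, missed the threshold (0.0589). III, IV, V and X lay above expectation in each replicate, but those past the threshold differed. They were III and V in replicate 1 (permutation test, adjusted p = 0.00014 and 3e-05), where IV and X missed it (0.199 and 0.719). In replicate 2 they were IV, V and X (0.00012, 0.0268 and 0.00427), where III missed it (0.548). No test compared the replicates. The strongest combined region in neither replicate, II 5328520 to 5341874 (q = 8.93e-47), was also the widest of the list at 13355 bp. Whether extra transgene copies contribute there was not tested. Of the 20 strongest regions in neither replicate, 13 lay on II. With q at most 1e-10, 52 of 62 regions on II were found in a replicate against 377 of 384 on the other chromosomes (Fisher's exact test, two-sided, p = 1.2e-05). The permutation and Fisher's tests of recovery take peaks as independent, and they were not repeated with close peaks counted once. Their p-values may therefore be too small.

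**Figure D3:**
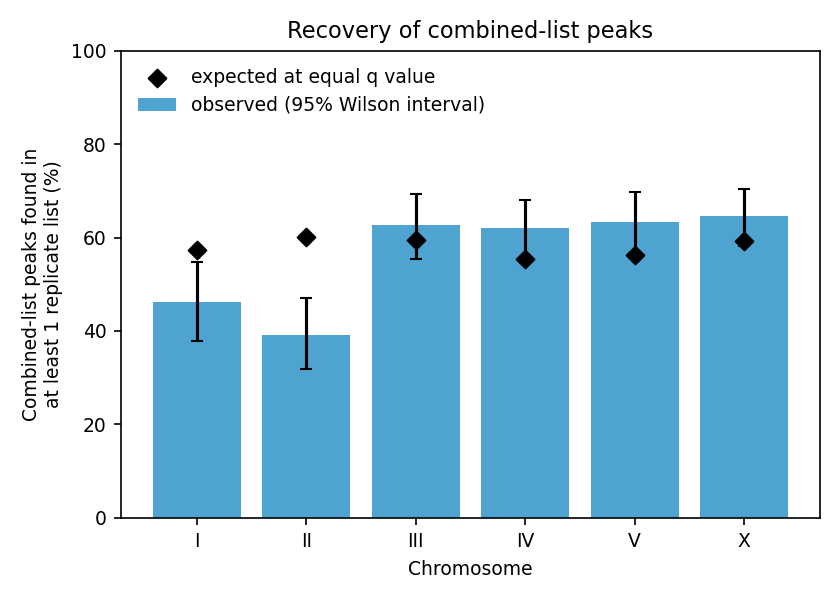
Bars show the percentage of combined-list peaks on each chromosome that overlap a peak of at least 1 replicate, with 95% Wilson intervals, and diamonds show the percentage expected from the q values of that chromosome's peaks. Chromosomes I (46.2%) and II (39.2%) lie below their expected values, and the other chromosomes lie between 62.1% and 64.5%.

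The called NHR-21 peaks were spread unevenly over the chromosomes. At equal combined q value, peaks on I and II were found in a replicate less often than expected, as given above. These shares can therefore reflect the calls as well as binding. In the combined list X held 234 peaks, or 20.6% against 17.8% expected from its length, IV held 240 or 21.1% against 17.4%, and III held 182 or 16.01% against 13.8%. Chromosome V held 191 or 16.8% against 20.9% expected, and I held 132 or 11.6% against 15.03%. These departures passed two-sided exact binomial tests adjusted over the 6 chromosomes, with adjusted p of 0.0242 for X, 0.0023 for IV, 0.042 for III, 0.0023 for V and 0.0023 for I. On II, 158 peaks or 13.9% stood against 15.1% (adjusted p = 0.264). The distribution as a whole had a chi-square of 37.2 (permutation p = 1e-05). These tests take peaks as independent. With peaks within 5 kb of each other counted as 1, 853 remained, and the exact binomial tests gave adjusted p of 0.0379 for X, 0.0379 for IV, 0.0379 for III, 0.0251 for V and 0.0251 for I, in the same directions. The lower share of I passed the test in the combined list, its strongest 50% and both replicate lists, and so did the higher share of X. By the same exact binomial test, the call on III did not hold in the strongest 50% (adjusted p = 0.089) or in replicate 2 (0.0507), that on IV in the strongest 50% (0.267) or in replicate 1 (0.0933), and that on V in replicate 2 (0.0851) or in replicate 1 (0.761), where the share of V was above its expectation by 0.62 percentage points. On II the replicate lists fell below expectation, at 5.87% of replicate 1 and 9.67% of replicate 2 (exact binomial test, adjusted p = 6.13e-08 and 0.00012). Shares sum to 100%, so the deficits of I and II raise the shares of the other chromosomes, and the lists were tested again without them. With II left out, the lower share of I still passed the exact binomial test (adjusted p = 0.00107 in the combined list, 2.48e-05 in replicate 1 and 2.07e-06 in replicate 2). With I and II left out, X held 27.6% against 25.5% expected in the combined list, 26.1% in replicate 1 and 28.1% in replicate 2, and none of these passed (exact binomial test, adjusted p = 0.207, 0.853 and 0.221). The excess of X can therefore not be told apart from the deficits of I and II. The excess of III was also no longer past the threshold in the combined list (exact binomial test, adjusted p = 0.211), while that of IV was in the combined list (0.0423) but in neither replicate 1 (0.853) nor replicate 2 (0.056). The share of V was below its expectation in all 3 lists by this count, at 22.6%, 25.2% and 22.3% against 29.9% (exact binomial test, adjusted p = 7.16e-06 in the combined list, 0.122 in replicate 1 and 0.000428 in replicate 2). Chromosome lengths were taken as the largest peak end, between 13.7 Mb for III and 20.8 Mb for V, since the headers give none.

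Peaks lay more often in the middle of the chromosomes than at their ends. The central 50% of the chromosomes held 718 of 1137 combined-list peaks, or 63.1% (60.3 to 65.9%, exact binomial test against an even spread, two-sided, p = 6.17e-19). The share was 71.7% on V, 69.8% on III, 68.2% on I, 65.2% on II and 59.2% on IV, and X stood at 50.9% (44.5 to 57.2%). Because neighbouring peaks are not independent, the whole pattern was also shifted along each chromosome, which gave permutation p = 0.0022 for the combined list, 0.0023 for replicate 2 and 0.069 for replicate 1, where the central share was 58.4%. Peaks also lay close together. A neighbour within 5 kb was present for 471 combined-list peaks, or 41.4% (38.6 to 44.3%), against 13.3% on average and at most 18.9% when the same peaks were placed at random on their chromosomes (one-sided permutation p = 0.0001, the smallest these placements can give). The share was 35.8% in replicate 2 and 30.3% in replicate 1, against 8.3% and 5.42% at random. The caller can split 1 signal into several intervals, as at IV 8527292 to 8531064, which was 3 regions in replicate 1. Such pieces also count as neighbours, and the random placements treat every interval as separate. The random placements also spread peaks evenly along each chromosome. The denser middle of the chromosomes can therefore raise the observed share above theirs, and this was not tested. The shares do not tell split signals or this uneven spread from nearby binding sites.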

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

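Chosen after the result was seen were the alternatives that left out chromosome II, the 2 loci missing from the combined list or the strongest 5% of either replicate, those with unmerged intervals or with only the peaks found in a replicate, the chromosome shares with close peaks counted once or without chromosomes I and II, the recovery of the combined list without replicate 1 or 2, and all those on peak position, neighbours and recovery at equal q value. Replicate overlap (81.9 to 98.04% in the stricter or length-matched lists, 84.4% with reciprocal overlap of 50% and 73.8% with centres within 200 bp), rank agreement (rho 0.82 to 0.86), the stronger and wider shared peaks, the overall chromosome distribution, the central position, the closeness of peaks and the deficit of II at equal q value (recovered minus expected, -18.6 to -34.4 regions) kept their direction and stayed past the threshold under each alternative run, except that the central position of replicate 1 peaks missed it when tested by circular shifts (permutation p = 0.069) and the chromosome distribution of replicate 1 missed it without I and II (permutation p = 0.0915). The share of replicate 2 regions shared was 52.1% with reciprocal overlap, 45.6% by centres and 80.0% with equal list lengths. The share of combined-list peaks found in at least 1 replicate was 57.9%, and it was 54.2% with reciprocal overlap, 91.5% in the strongest 50% and 60.9% without chromosome II. It ranged from 34.04% without replicate 2 to 55.9% without replicate 1. The share of chromosome V was -4.09 percentage points from expectation in the combined list. The replicate lists gave -2.77 without replicate 1 and 0.62 without replicate 2, a reversal. With I and II left out, V stood at 25.2% against 29.9% expected in replicate 1 (exact binomial test, adjusted p = 0.122). Leaving out 2 chromosomes with low shares lowers the other shares against their expectations by arithmetic. That value therefore does not show that the reversal goes away. Chromosome II, -1.22 points in the combined list, was at -5.44 without replicate 1 and -9.24 without replicate 2. No paired analysis was possible because the replicate numbers pair ChIP with Input, and no Input values were analysed here. Other alternatives not run were a per-peak value other than q, gene numbers per chromosome, and those for promoters, noncoding genes, gene lists and sequence. Unknown depth limits what absence from a replicate list can mean: a peak not called was not detected at that depth and threshold.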

Other observations

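All but 1 of the tests of explanations in this part were chosen after the result was seen, the exception being the ratio of replicate to combined scores on chromosome II. Peaks of the combined list fell in 557 of 997 windows of 100 kb, and 36 windows held 5 or more, together 209 peaks or 18.4% of the list. The counts per window were not tested. The densest was X 13300001 to 13400000 with 10 peaks, 7 of them in both replicates. It was followed by X 11000001 to 11100000 and III 5900001 to 6000000 with 9 peaks each, of which 2 and 4 were in both replicates. A further 4 windows held 7 peaks each, those starting at V 11800001 with 6 peaks in both replicates, X 4100001 with 4, I 8800001 with 3 and II 7500001 with 1.

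The deficit of chromosome II in the replicate lists was not explained by its q values in the combined list: 62 regions were found where 95.2 were expected at equal q value. If the combined call scored II too high, its peaks could still be weaker than those q values, and this stays open. Nor did a single missing stretch explain it. With any 1 of 5 equal stretches of II left out, the regions recovered minus those expected stayed at -23.4 or lower (permutation p = 1e-05 each). The loci missing from the combined list lie on II and V, but V had no such deficit, with 121 regions against 107.7 expected. That expectation pools all chromosomes, so the deficits of I and II raise V above it. By plain share V stood at 63.4%, between 62.1% on IV and 64.5% on X. These values argue only against an effect of the loci on V like the deficit of II. Among peaks with combined q at most 1e-10 that the replicate also called, the median ratio of replicate to combined −log10 q was 0.26 on II (n = 22 of 62 peaks) against 0.43 elsewhere (n = 318 of 384) in replicate 1, and 0.44 (n = 51 of 62) against 0.62 (n = 373 of 384) in replicate 2 (two-sided permutation p = 1e-05 each). In the same way I was lower than III, IV, V and X, at 0.33 (n = 34 of 50 peaks) against 0.43 and 0.49 (n = 46 of 50) against 0.63. Peaks not called in a replicate have no ratio and are not described by these values. A called peak must pass the replicate's threshold, so its ratio has a floor that is higher for weaker combined peaks. The ratios were not compared at equal combined q value, so differences in peak strength can contribute to these gaps. The ratios rest on the same q values as the recovery counts, so they are not independent evidence for a cause of the deficit. A candidate explanation is a scaling of ChIP against control per chromosome that differed between the calls, which these lists cannot assign to the replicate calls or to the combined one, and no biological explanation was tested.

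The loci on II and V that are strong in both replicates were missing from the combined list although weaker peaks were in it. Of 552 replicate peaks with larger q values than any peak at these loci, 544 or 98.6% (Wilson interval 97.2 to 99.3%) were in the combined list, which argues against too weak a signal in the replicates as the cause. A possible explanation is that intervals around the loci were left out of the combined list. The test of it cannot decide: 0 of 6 other replicate peaks within 50 kb were missing, but only 8 of 1062 were missing outside the loci, so 0 would be the usual count at any place. Extra copies of a sequence on the transgene, or high signal in Input, might be why such intervals would be removed, and this stays untested because neither a WS180 annotation nor Input values were used here.

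The repeated lines of replicate 2 were not a plain doubling, since 200 intervals had no identical second line. Of these, 98% overlapped exactly 1 other, with log10 q values that differed by a median of 0.18, and 4 overlapped none. The 200 intervals fell on V (76), IV (56), III (24), X (24) and I (20), and 0 on II. A candidate explanation is that the lines of 2 nearly identical calls of the same library were joined. Counting lines in place of regions would make the list 1320 peaks long in place of 662.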
